A study of Mactra quadrangularis with 9 samples.

How the data were processed

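Messenger RNA was measured in gill of the clam *Mactra quadrangularis*, which the series text calls *Mactra veneriformis*, after 24 h at 7.5, 4 or 2 mg/L dissolved oxygen. Per the labels' protocols, water was held at 20 ± 1 °C and a salinity of 27, with 40 clams per parallel tank and oxygen kept within 0.2 mg/L of its target by nitrogen (hypoxia) or aeration (control) and measured every 4 h. The clams were not fed. Total RNA with an integrity number above 7.0 was selected with oligo(dT), made into libraries with a dUTP second strand, and sequenced as pairs of 150 bp on an Illumina NovaSeq. Whether strand was used in counting, and how many clams went into each library, is not given in the sources used here. The labels give 1 batch date for the 9 libraries.

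The deposited table holds, for 24722 genes and 9 libraries, raw counts and FPKM side by side, 18 columns of values in all, and each of them was used. The authors' counts are whole numbers per gene with no normalization, per the file headers. The authors' FPKM values are scaled for gene length and for the number of mapped fragments, per the file headers, and any further scaling is not given in the sources used here. Reads were processed with cutadapt 1.9, HISAT2 2.2.1 and StringTie 2.1.6, per the submitters' processing notes, which also name DESeq2 and edgeR without saying where they were used. Counts and FPKM were 0 in exactly the same cells. Among low values, even counts were more frequent than odd ones (2649 cells held a count of 2 and 1855 a count of 1, 3567 held a 4 and 1914 a 3), so a count is not 1 independent molecule. A floor for a group with 0 counts treats counts as independent, so a fold bound computed from it may be too high. SDs and standard errors also hold the spread between libraries. Gene coordinates are those of the deposited table, and the genome build is not given in the sources used here. Gene names are the descriptions in that table: 13677 genes had an informative one, 3912 had none, and copies that share a description may share reads.

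Library totals ran from 26994566 to 32246147 counts. Genes with a mean of at least 1 FPKM over the 9 libraries were tested, which left 15397. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts with TMM scaling, 1 coefficient per group, all 9 libraries in the fit and Benjamini-Hochberg adjustment over the genes tested. A gene was called changed at an adjusted p under 0.05, with no fold threshold. The design written before the data were examined had assumed a table of FPKM alone and named limma (3.58.1) on log2(FPKM + 1). It also said that edgeR would be used if the table held counts, so the limma test became an alternative. Levels are given as TMM-scaled CPM, counts scaled to library size, mean ± SD over 3 libraries. Fold changes are ratios from the fitted model, and standard errors were derived from the fitted log2 fold change and its F statistic. Where a group had 0 counts in its 3 libraries, the fold is a bound computed against a floor of 3 counts over the group. The common biological coefficient of variation was 11.8%.

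The same script was tested on simulated counts with 200 genes changed by known folds in each comparison, drawn from the 15397 genes tested. For 4 against 7.5 mg/L it called 26% of genes changed 1.25-fold, 48% at 1.5-fold, 80% at 2-fold and 100% at 4-fold. For 2 against 7.5 mg/L the shares were 24%, 46%, 84% and 100%, and for 2 against 4 mg/L they were 14%, 52%, 78% and 100%. Of the unchanged genes, 0.073%, 0.086% and 0.073% were called. In these simulations a change of 1.5-fold was therefore missed in about as many genes as it was found. The simulated counts held these 200 changed genes per comparison and a smaller mock list that was also raised and entered none of these shares. The deposited counts, in contrast, gave 10760, 9771 and 9813 called genes in the same order. The Benjamini-Hochberg cut on p is looser when more genes change. These shares therefore need not hold for the real comparisons, and how many real changes were missed was not measured.

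Gene lists were written before the data were examined as word patterns matched to the descriptions. They comprised 21 lists of genes and 7 lists of markers of cell types that a gill sample could hold. The gene lists were HIF pathway and oxygen sensing, glycolysis, anaerobic succinate, opine and gluconeogenic enzymes, tricarboxylic acid cycle, oxidative phosphorylation, heat shock proteins, endoplasmic reticulum stress, antioxidant and glutathione, apoptosis and inhibitors of apoptosis, autophagy and mitophagy, innate immune sensing and effectors, immediate early and stress kinase genes, cytosolic ribosomal proteins, proteasome and ubiquitin, DNA replication and cell cycle, histones, fatty acid and lipid metabolism, globins with carbonic anhydrases and nitric oxide synthase, xenobiotic metabolism, solute carriers and ion pumps, and extracellular matrix and adhesion. The marker lists were cilia, muscle, gonad, digestive gland, hemocyte, mantle and shell, and neuron. Each list was compared with the other genes by limma's camera on log2(FPKM + 1) with a preset correlation of 0.01, adjusted over the 28 lists of a comparison. Camera with a correlation estimated per list is given beside each call. Because camera used deposited FPKM and the gene test used TMM scaling, a list's direction can differ between them. Some patterns caught genes that do other work than the list's name says. The glycolysis list holds ketohexokinases and a D-lactate dehydrogenase, and the heat shock list is mostly copies of HSP70 12A and 12B. The hemocyte list shares integrins with the matrix list, and the xenobiotic list holds carbohydrate sulfotransferases. The digestive gland list holds several cathepsin L genes, which need not be specific to that tissue. Malate and citrate enzymes sit in more than 1 list. The chaperone hypoxia up-regulated protein 1 sits in both the HIF and the endoplasmic reticulum stress list.

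The genes named were chosen by a rule also written in advance: in each comparison the 8 largest rises and 8 largest falls of log2(FPKM + 1) among called, fully separated genes with an informative description and at least 5 FPKM in the higher group, up to 4 members per list with the smallest adjusted p, and 16 sentinel genes of hypoxia and stress, of which 15 were listed and a VHL gene was not found by its pattern. The rule gave 229 genes, and the text names part of them.

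The comparisons were 4 against 7.5 mg/L, 2 against 7.5 mg/L and 2 against 4 mg/L, each 3 libraries against 3. Any statement that both oxygen levels differed rests on the last of these. An overlap of the first 2 comparisons was set beside 20 simulations of unchanged groups that share the control libraries, and beside the overlap of independent lists. Alternatives tried were other pseudocounts, filters, scalings (median-of-ratios, total counts, quantile), thresholds, spread models, array weights, a replicate block, fits on the 2 groups compared alone, each library left out in turn, DESeq2 1.42.0 and other list tests. The edgeR scalings, DESeq2, limma on log2(FPKM + 1) as an alternative and camera on log2 CPM were chosen after the data were seen. Libraries within a group were checked for duplicates by a chi-square of their counts, which gave 5.78 to 8.3 per degree of freedom within groups and 235 to 333 between groups, and none was merged.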

Results

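Gill transcriptomes of *Mactra quadrangularis*, a marine surf clam, were profiled by poly(A) RNA sequencing after 24 h in water with 7.5 mg/L (control), 4 mg/L or 2 mg/L dissolved oxygen, with 3 libraries per group and 9 in all. Total counts were 26994566, 31962737 and 32246147 in the control libraries, 31831843, 31867946 and 32233882 at 4 mg/L, and 31520811, 31423730 and 27391930 at 2 mg/L. Between 20316 and 20958 genes had a count in a library. Across genes, libraries of 1 group correlated at 0.989 to 0.991, control with 2 mg/L at 0.885 to 0.889, control with 4 mg/L at 0.831 to 0.834 and 4 with 2 mg/L at 0.838 to 0.844. The first principal component held 57.4% of the variance and set the 4 mg/L libraries apart, and the second held 36.1% and separated control from 2 mg/L. The labels do not say that the 3 libraries of a group came from separate clams, so the p-values measure only the spread between these libraries, which may be technical. Of 15397 genes tested, 12973 (84.3%) differed between at least 1 pair of groups.

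The first comparison asked what changed in gill at 4 mg/L oxygen relative to 7.5 mg/L. A cytosolic phosphoenolpyruvate carboxykinase (PEPCK, Mve06G010350, chromosome 6, 34103329 to 34112237), the enzyme that interconverts oxaloacetate and phosphoenolpyruvate, rose 18.6-fold from 268 ± 11.4 to 5001 ± 159 CPM (mean ± SD, n = 3). HIF-1alpha (Mve02G016380), the oxygen-regulated subunit of the hypoxia-inducible factor, rose 2.72-fold from 93.1 ± 2.88 to 253 ± 8.16 CPM. The endoplasmic reticulum chaperone GRP78 (Mve14G007880) rose 2.31-fold from 774 ± 21.3 to 1787 ± 40.7 CPM. Genes for the translation and ciliary machinery went the other way: 58 of 63 cytosolic ribosomal protein genes and 45 of 80 cilia genes fell (adjusted p = 0.428 for each with an estimated correlation).

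Of the 15397 genes, 10760 (69.9%) changed by edgeR's quasi-likelihood test at the adjusted p threshold of 0.05, 5447 upward and 5313 downward. At least 2-fold changes were found in 5027 genes, 2753 upward and 2274 downward. The 3 libraries of each group were fully separated for 74.2% of genes, where chance gives 10%.

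All 5 tested members of the HIF and oxygen sensing list rose (camera adjusted p = 0.0312, adjusted p = 0.428 with an estimated correlation). Besides HIF-1alpha these included an EGLN1-like prolyl hydroxylase (Mve02G014470), whose family marks HIF-alpha for degradation, at 27.6 ± 1.49 and 64.7 ± 2.34 CPM (2.34-fold). The chaperone hypoxia up-regulated protein 1 (HYOU1, Mve07G000120), at 24.1 ± 1.49 and 49.0 ± 0.964 CPM (2.03-fold), was another member. It is also counted in the endoplasmic reticulum stress list. The HIF partner ARNT (Mve10G004750) rose from 37.4 ± 4.21 to 52.7 ± 3.15 CPM (1.41-fold). Of 19 enzymes of anaerobic succinate, opine and gluconeogenic metabolism, 13 rose, 4 fell and 2 did not pass (camera adjusted p = 0.0312, adjusted p = 0.428 with an estimated correlation). They included 2 further PEPCK genes that lie beside the first on chromosome 6, Mve06G010330 at 2.62-fold and Mve06G010340 at 1.75-fold, a mitochondrial malate dehydrogenase (Mve11G006600) at 1.84-fold. The alternative oxidase (Mve07G002200), which passes electrons to oxygen without pumping protons, rose 2.25-fold (52.8 ± 2.58 to 119 ± 9.29 CPM).

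Glycolysis as a list was not called (6 rose, 4 fell, 7 did not pass; camera adjusted p = 0.625), although several members rose. Hexokinase type 2 (Mve13G001100) rose 2.95-fold from 122 ± 3.94 to 359 ± 3.94 CPM, a fructose-bisphosphate aldolase (Mve11G002450) 1.93-fold and triosephosphate isomerase (Mve04G013470) 1.62-fold. Phosphofructokinase (Mve18G003940), which commits sugar to glycolysis, rose from 34.0 ± 2.72 to 39.5 ± 0.730 CPM (adjusted p = 0.0394), a call lost under total-count scaling and in most sets with a library left out. The tricarboxylic acid cycle (11 rose, 6 fell, 6 did not pass of 23; adjusted p = 0.682) and oxidative phosphorylation (11 rose, 14 fell, 15 did not pass of 40; adjusted p = 0.464) were not called. With total counts 8 rose and 6 fell in the tricarboxylic acid cycle and 6 rose and 15 fell in oxidative phosphorylation, and with quantile-normalised FPKM 4 rose and 5 fell in glycolysis and 5 rose and 19 fell in oxidative phosphorylation.

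In the endoplasmic reticulum stress list 17 of 21 genes rose, 2 fell and 2 did not pass (camera adjusted p = 0.00495, adjusted p = 0.22 with an estimated correlation). An asparagine synthetase (Mve11G004020) rose 1.95-fold, a protein disulfide-isomerase (Mve01G015760) 1.47-fold and calreticulin (Mve03G001600), a calcium-binding chaperone, 1.38-fold from 1687 ± 14 to 2333 ± 85.5 CPM. Of 47 immediate early and stress kinase genes, 27 rose, 10 fell and 10 did not pass (camera adjusted p = 0.0433, adjusted p = 0.297 with an estimated correlation). The call ended without control replicate 2 (adjusted p = 0.0551) or 4 mg/L replicate 2 (0.05) or 3 (0.0512), under median-of-ratios scaling of FPKM (0.052) and with genes of at least 5 FPKM (0.273). The stress transcription factors C/EBP beta (Mve06G004740) and ATF3 (Mve02G003040) rose 2.64-fold (1810 ± 19.4 to 4778 ± 259 CPM) and 2.92-fold (63.6 ± 2.77 to 186 ± 2.40 CPM). Early growth response 1 (EGR1, Mve13G000680), another factor of this class, was 7.98-fold lower, at 3.15 ± 0.884 against 25.1 ± 2.70 CPM.

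Ribosomal protein genes moved down together by a median of -0.39 on the log2 scale, with 1 of 63 rising (camera adjusted p = 2.92e-11, adjusted p = 0.428 with an estimated correlation). L7a (Mve14G007890) fell from 3220 ± 50.1 to 2263 ± 97.5 CPM and L3 (Mve01G020490) from 2977 ± 59 to 2025 ± 120 CPM. The exception was a copy of S6 (Mve10G002420), which rose 2.05-fold while another S6 copy on the same chromosome (Mve10G002520) was 1.94-fold lower. Copies may share reads, which was not tested here. Among 80 cilia genes, markers of the ciliated gill epithelium, 45 fell, 11 rose and 24 did not pass (camera adjusted p = 0.00875, adjusted p = 0.428 with an estimated correlation). Most of these changes were small: the median was -0.2 on the log2 scale, and only 3 fell and 2 rose at least 2-fold. The largest falls included axonemal dynein heavy chains 5 (Mve06G002780, 2.55-fold lower) and 3 (Mve08G006600, 2.83-fold lower), motors of ciliary beating. An axonemal dynein light chain 1 (Mve02G017430) rose 9.48-fold.

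Digestive gland markers moved at 4 mg/L: 13 of 21 rose, 3 fell and 5 did not pass (camera adjusted p = 0.0433, adjusted p = 0.308 with an estimated correlation), and the list was not called on log2 CPM (adjusted p = 0.194). The call also ended without control replicate 2 (adjusted p = 0.0551) or 3 (0.0569) or 4 mg/L replicate 2 (0.05) or 3 (0.0512). Cathepsin L1-like (Mve17G004030) was at 3.50 ± 0.198 and 43.7 ± 2.64 CPM and a pancreatic triacylglycerol lipase (Mve03G019360) at 39.3 ± 1.57 and 80.9 ± 6.85 CPM. Another lipase of this type (Mve18G004440) was lower, at 295 ± 13.1 and 155 ± 5.89 CPM. Adjusted over the list alone, the counts of rises and falls in these 7 called lists were the same as those adjusted over all genes.

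The largest rises by the rule lay outside the HIF and anaerobic lists. ADP-ribosylation factor 1 (Mve02G016680), a GTPase of vesicle traffic, rose 48.9-fold from 30.9 ± 2.45 to 1509 ± 25.6 CPM. A gene described by sushi, von Willebrand and pentraxin domains (Mve02G010780), found in adhesion proteins, rose 45.9-fold from 30.7 ± 3.71 to 1408 ± 17.4 CPM, and DMRT4 (Mve03G009340), of a family of sex-determination transcription factors, 105-fold from 1.75 ± 0.947 to 184 ± 16.5 CPM. Falls named by the rule included a leucine-rich repeat protein (Mve04G004040, 159-fold lower), a complement C1q-like protein (Mve05G003140, 25.5-fold lower). Nephrin (Mve04G012430), an adhesion protein, went from 7.15 ± 0.635 CPM to 0 counts in all 3 libraries. Against the floor of 3 counts it was at least 230-fold lower, a bound that may be too high.

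Among the other sentinels, the HSP70 gene (Mve07G002840) was 1.32-fold lower and HSP90 (Mve01G001290) 1.82-fold higher. The mitophagy receptor BNIP3 (Mve13G003520) rose 5.09-fold from 2.57 ± 0.818 to 13.0 ± 1.44 CPM. Lists without a call included heat shock proteins (53 rose, 53 fell of 128), antioxidant and glutathione (17 rose, 22 fell of 51), apoptosis (36 rose, 23 fell of 81), autophagy (8 rose, 9 fell of 21), innate immunity (52 rose, 71 fell of 153), fatty acid and lipid metabolism (23 rose, 10 fell of 42), xenobiotic metabolism (43 rose, 33 fell of 98) and solute carriers (69 rose, 48 fell of 147). DNA replication (4 rose, 13 fell of 28; camera adjusted p = 0.254) and muscle (12 rose, 13 fell of 30; camera adjusted p = 0.777) were also among them. Median, mean and camera direction differed in sign for the antioxidant, proteasome, histone, globin, muscle, gonad and neuron lists.

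**Figure D1:**
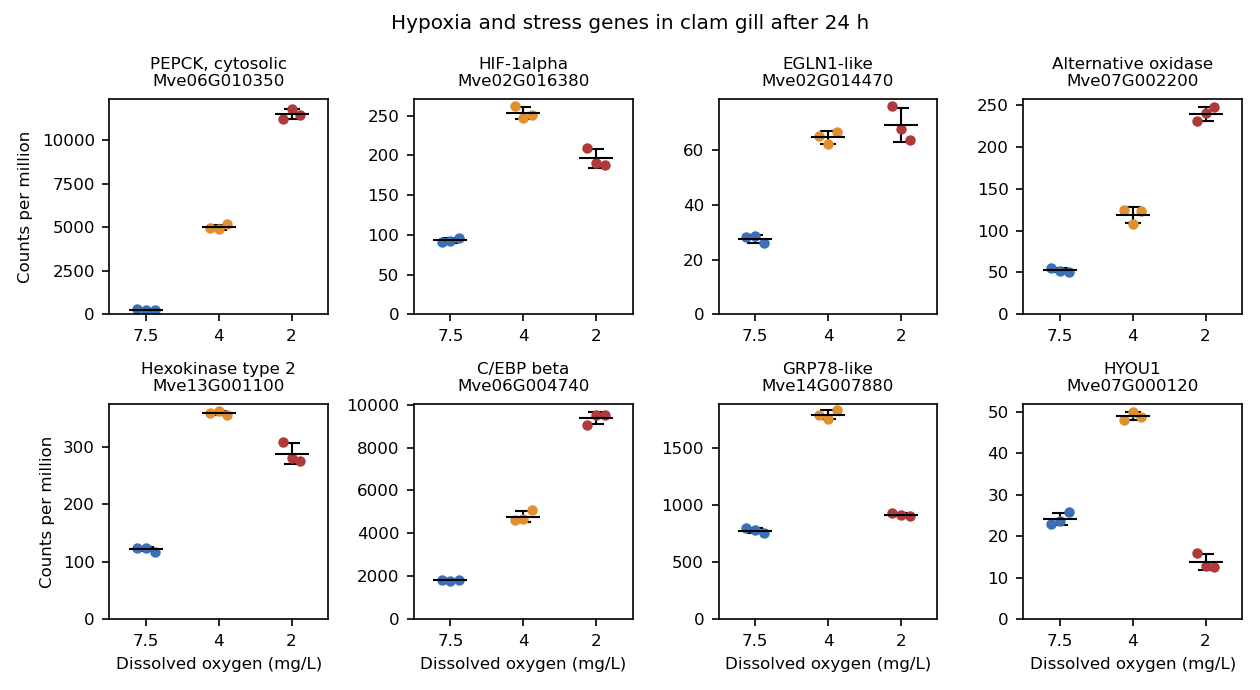
Level in TMM-scaled CPM (vertical axes, linear, from 0) of 8 genes at 7.5, 4 and 2 mg/L dissolved oxygen; points are the 3 libraries of a group, the long bar is their mean and the whiskers 1 SD. PEPCK, alternative oxidase and C/EBP beta were highest at 2 mg/L and HIF-1alpha, hexokinase type 2, GRP78 and HYOU1 at 4 mg/L.

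The second comparison asked what changed at 2 mg/L relative to 7.5 mg/L. PEPCK (Mve06G010350) rose 42.9-fold, from 268 ± 11.4 to 11500 ± 291 CPM, and the alternative oxidase (Mve07G002200) 4.54-fold, from 52.8 ± 2.58 to 240 ± 8.01 CPM. Heat shock protein 22 (Mve16G010930), a small chaperone, rose 26.4-fold, from 3.50 ± 0.215 to 92.2 ± 12.4 CPM. Of 28 genes of DNA replication, 16 fell and 2 rose (adjusted p = 0.118 with an estimated correlation), with the helicase subunit MCM5 (Mve02G013640) 7.01-fold lower at 6.34 ± 0.743 against 44.6 ± 1.53 CPM. In the same libraries 17 of 30 muscle markers rose and 5 fell (adjusted p = 0.0816 with an estimated correlation), with paramyosin (Mve09G008510), a filament protein of molluscan muscle, at 363 ± 10.3 and 3000 ± 442 CPM.

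By edgeR's quasi-likelihood test 9771 of 15397 genes (63.5%) changed, 4847 upward and 4924 downward, and 3872 of them at least 2-fold (2131 upward, 1741 downward). Scaling by total counts in place of TMM shifted the median log2 change by -0.199 and split the calls into 3709 upward and 6621 downward, 35.9% upward against 49.6%. Groups were fully separated for 68.3% of genes against 10% by chance.

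Of the HIF list, 4 of 5 genes rose and 1 fell, and the list was not called (camera adjusted p = 0.188). HIF-1alpha (Mve02G016380) rose 2.11-fold to 196 ± 11.9 CPM and the EGLN1-like gene (Mve02G014470) 2.51-fold to 69.2 ± 6.35 CPM, whereas HYOU1 (Mve07G000120) fell to 13.8 ± 1.92 CPM, 1.75-fold lower. In the anaerobic enzyme list 10 rose, 5 fell and 4 did not pass (adjusted p = 0.134), and in glycolysis 6 rose and 9 fell of 17 (adjusted p = 0.656). In the tricarboxylic acid cycle 7 rose and 7 fell of 23 (adjusted p = 0.488), and in oxidative phosphorylation 10 rose and 8 fell of 40 (adjusted p = 0.0577). These counts rested on scaling: with total counts 3 rose and 12 fell in the tricarboxylic acid cycle, 4 rose and 23 fell in oxidative phosphorylation, and 8 rose and 7 fell in the anaerobic list. Oxidative phosphorylation was called as lower under 6 of 18 alternative settings against the other genes, but not with an estimated correlation (adjusted p = 0.51). Hexokinase type 2 (Mve13G001100) rose 2.37-fold and hexokinase-1-like (Mve13G007880) 2.56-fold.

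In the immediate early and stress kinase list 30 of 47 genes rose and 2 fell, 31 and 2 adjusted over the list alone (camera adjusted p = 4.38e-05, adjusted p = 0.0375 with an estimated correlation). It was the only list called both ways in the 3 comparisons. C/EBP beta (Mve06G004740) rose 5.18-fold to 9379 ± 272 CPM, ATF3 (Mve02G003040) 5.50-fold to 350 ± 11 CPM. The AP-1 component fos-related antigen 1 (Mve02G005320) rose 4.17-fold to 287 ± 2.96 CPM and Krueppel-like factor 5 (Mve09G010340) 2.45-fold to 3243 ± 23 CPM. EGR1 (Mve13G000680) was 1.55-fold lower than in control, at 16.2 ± 2.30 CPM.

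Of 128 heat shock genes 70 rose, 36 fell and 22 did not pass, 52 and 45 with total counts (camera adjusted p = 0.0261, adjusted p = 0.0816 with an estimated correlation). Besides HSP22, a DnaJ B4-like cochaperone (Mve03G003290) rose 10.7-fold to 188 ± 5.47 CPM and BAG3 (Mve18G003920), which links chaperones to autophagy, 5.2-fold to 147 ± 11.2 CPM. An HSP70 12B-like gene (Mve09G013150) was 17.5-fold lower. In the apoptosis list 34 of 81 rose, 15 fell and 32 did not pass, 31 and 24 with total counts (camera adjusted p = 0.0284, adjusted p = 0.131 with an estimated correlation), and its rises included inhibitors of cell death. Bcl-2-like 1 (Mve12G003320) rose 5.51-fold to 375 ± 5.56 CPM and 2 inhibitors of apoptosis on chromosome 5 rose 4.10-fold (Mve05G013220) and 4.18-fold (Mve05G013130). Autophagy genes rose in 14 of 21 cases, 3 fell and 4 did not pass (camera adjusted p = 0.0261, adjusted p = 0.262 with an estimated correlation). The cargo receptor sequestosome-1 (Mve09G009650) rose 2.41-fold to 1431 ± 14.6 CPM and autophagy-related protein 13 (Mve09G010860), part of the initiating kinase complex, 1.95-fold.

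Muscle markers went up in 17 of 30 genes, 18 adjusted over the list alone, and down in 5 (camera adjusted p = 0.000843, adjusted p = 0.0816 with an estimated correlation). Tropomyosin (Mve10G006090) was at 855 ± 13.2 and 2616 ± 309 CPM and striated myosin heavy chain (Mve01G015220) at 376 ± 18.7 and 1615 ± 215 CPM. Beside this, 31 of 58 matrix and adhesion genes rose and 17 fell, 18 adjusted over the list alone (camera adjusted p = 0.0207, adjusted p = 0.262 with an estimated correlation). Integrin beta-like protein A (Mve02G003930), a matrix receptor, was at 712 ± 11.5 and 2867 ± 40.0 CPM, and collagen alpha-2(I)-like (Mve01G005090) at 1586 ± 24.9 and 4501 ± 67.4 CPM. Mantle and shell markers rose in 9 of 17 genes and fell in 4 (camera adjusted p = 0.0284, adjusted p = 0.296 with an estimated correlation), but were not called on log2 CPM (adjusted p = 0.227). A tyrosinase (Mve06G013920), an enzyme of shell pigment and periostracum formation, was at 3.17 ± 2.11 and 240 ± 20.8 CPM and a shell matrix protein (Mve11G012680) at 0.257 ± 0.445 and 73.4 ± 1.94 CPM.

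In the DNA replication and cell cycle list 16 of 28 genes fell, 2 rose and 10 did not pass (camera adjusted p = 0.00651, adjusted p = 0.118 with an estimated correlation). They included the sliding clamp PCNA (Mve01G002720), 3.83-fold lower at 14.1 ± 0.927 CPM, and MCM7 (Mve15G000520), 6.12-fold lower. Ribosomal protein genes fell in 40 of 63 cases and rose in 4 (camera adjusted p = 4.86e-07, adjusted p = 0.361 with an estimated correlation). Antioxidant and glutathione genes fell in 25 of 51 cases and rose in 11 (camera adjusted p = 0.0467, adjusted p = 0.262 with an estimated correlation). This call ended when 4 mg/L replicate 1 (adjusted p = 0.0545) or 2 (0.0537) was left out of the fit, and under median-of-ratios (0.0524) and quantile (0.0602) scaling. Glutathione S-transferase A (Mve02G015270) fell from 210 ± 2.64 to 109 ± 1.33 CPM, while an extracellular copper/zinc superoxide dismutase (Mve05G004020) went from 0.133 ± 0.141 to 88.2 ± 4.23 CPM. Catalase (Mve05G008150) was at 106 ± 4.61 and 120 ± 2.99 CPM (log2 change 0.19 ± 0.05), a direction that turned to -0.01 under total-count scaling. Cilia genes fell in 36 of 80 cases and rose in 18 (camera adjusted p = 0.0282, adjusted p = 0.361 with an estimated correlation), and were not called on log2 CPM (adjusted p = 0.16). For the heat shock, apoptosis, autophagy, mantle, ribosomal, DNA replication, antioxidant and cilia lists the counts adjusted over the list alone were the same.

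The largest rises by the rule included a saxiphilin-like protein (Mve07G007230), of the transferrin family, from 0.586 ± 0.203 to 71.3 ± 6.52 CPM and caprin-2 (Mve12G008300), an RNA-binding protein, 40.9-fold to 276 ± 10.2 CPM. Temptin (Mve01G008120), described in molluscs as a secreted pheromone protein, had 0 counts in the control libraries and 21 ± 0.94 CPM at 2 mg/L. Against the floor of 3 counts it was at least 677-fold higher, a bound that may be too high. Among the largest falls, serum amyloid A (Mve08G001030), an acute-phase protein, dropped 10.3-fold from 834 ± 22.3 to 81.2 ± 5.75 CPM. A TRIM2-like gene (Mve11G002980) went from 29.9 ± 2.01 CPM to 0 counts, at least 830-fold lower with the same limit on the bound. Lists without a call included endoplasmic reticulum stress (8 rose, 8 fell of 21; adjusted p = 0.955), innate immunity (57 rose, 49 fell of 153; adjusted p = 0.48) and proteasome and ubiquitin (28 rose, 43 fell of 107; adjusted p = 0.0987). The same held for histones (3 rose, 2 fell of 5; adjusted p = 0.982), fatty acid metabolism (16 rose, 13 fell of 42; adjusted p = 0.955) and xenobiotic metabolism (33 rose, 28 fell of 98; adjusted p = 0.652). Solute carriers (35 rose, 54 fell of 147; adjusted p = 0.652) and globins with carbonic anhydrases (9 rose, 4 fell of 23; adjusted p = 0.257) were also not called. With total counts the balance turned for innate immunity (48 rose, 60 fell), fatty acid metabolism (11 rose, 15 fell) and xenobiotic metabolism (27 rose, 38 fell). Digestive gland markers fell in 13 of 21 cases and rose in 4, with a median log2 change of -1.22, and the list was not called (adjusted p = 0.13). Median, mean and camera direction differed in sign for the tricarboxylic acid cycle, oxidative phosphorylation, endoplasmic reticulum stress, histone, fatty acid, xenobiotic, solute carrier and hemocyte lists.

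**Figure D2:**
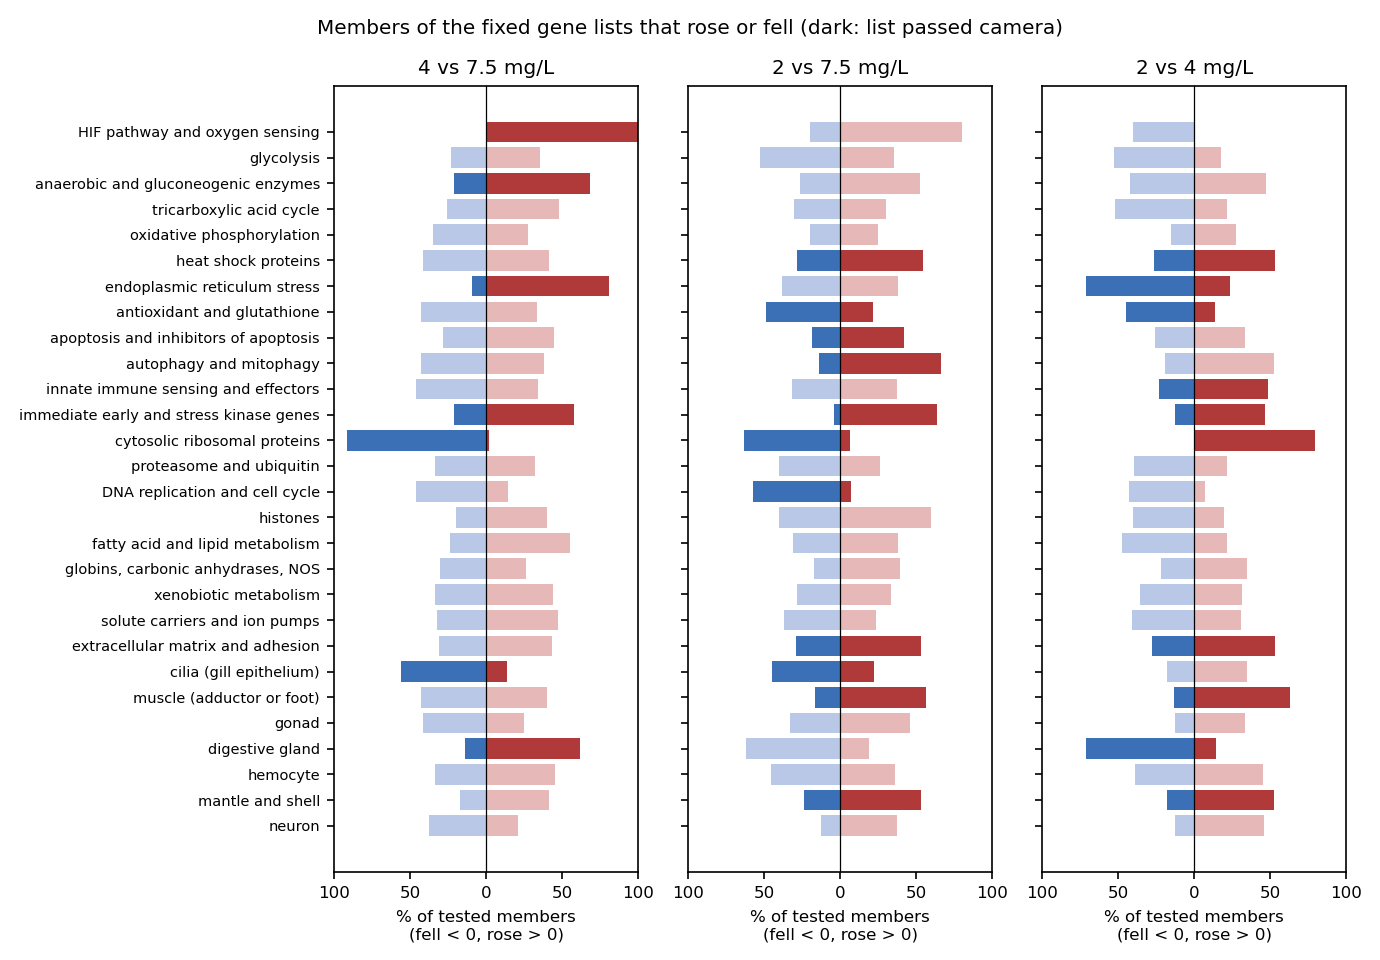
Percent of tested members of each of the 28 fixed lists that rose (right, red) or fell (left, blue) in 3 comparisons by the edgeR test; dark bars mark lists called by camera with the preset correlation. With an estimated correlation, the immediate early list at 2 against 7.5 mg/L was the only one called.

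The third comparison, 2 against 4 mg/L, asked directly whether both oxygen levels differed in gill. PEPCK (Mve06G010350) was a further 2.30-fold higher at 2 mg/L and the alternative oxidase (Mve07G002200) 2.01-fold higher, while HIF-1alpha (Mve02G016380) was 1.29-fold lower, GRP78 (Mve14G007880) 1.96-fold lower and HYOU1 (Mve07G000120) 3.56-fold lower. C/EBP beta, ATF3 and fos-related antigen 1 were 1.96-, 1.88- and 2.09-fold higher. Most replication genes that differed were lower at 2 mg/L, and most muscle markers that differed were higher.

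The edgeR quasi-likelihood test called 9813 genes (63.7%), 4871 higher and 4942 lower at 2 mg/L, and 4159 at least 2-fold (2145 higher, 2014 lower). Total-count scaling shifted the median by -0.13 and split the calls into 4040 higher and 6002 lower, 40.2% higher against 49.6%. Groups were fully separated for 68% of genes, against 10% by chance. Camera called 10 lists, none of them with an estimated correlation.

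In the endoplasmic reticulum stress list 15 of 21 genes were lower at 2 mg/L and 5 higher (camera adjusted p = 0.0333, adjusted p = 0.168 with an estimated correlation). The folding enzymes protein disulfide-isomerase A3 (Mve10G009610) and A4 (Mve12G009000) were lower, at 456 ± 12.4 and 192 ± 2.29 CPM and at 90.4 ± 1.78 and 33.2 ± 2.13 CPM. Another gene described as A3 on the same chromosome (Mve10G006490) went the other way. Its summed counts were 445 in control, 0 at 4 mg/L and 87 at 2 mg/L. The regulators XBP1 (Mve11G010540) and tribbles 2 (Mve18G004270) were higher, at 2213 ± 34.4 and 3460 ± 93.2 CPM and at 1021 ± 7.96 and 1595 ± 4.47 CPM. Heat shock genes were higher in 68 of 128 cases and lower in 34, 69 and 37 adjusted over the list alone (camera adjusted p = 0.00932, adjusted p = 0.0786 with an estimated correlation). Many were HSP70 12A and 12B copies, a large bivalve family, such as Mve09G007120 (4.95 ± 0.943 and 47.3 ± 1.31 CPM) and Mve09G000170 (3.20 ± 1.1 and 39.2 ± 1.45 CPM).

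Innate immune genes were higher in 74 of 153 cases and lower in 35, 75 and 35 adjusted over the list alone (camera adjusted p = 0.0199, adjusted p = 0.211 with an estimated correlation). Interferon-induced protein 44-like (Mve14G007110) was at 57.4 ± 3.45 and 339 ± 32.6 CPM, a toll-like protein (Mve11G009450), of the pattern receptor family, at 1.38 ± 0.226 and 48.3 ± 4.41 CPM, and a C1q-domain gene (Mve06G002060) at 5.78 ± 0.819 and 53.8 ± 2.52 CPM. The recognition lectin ficolin-2-like (Mve03G002320) went from 78.7 ± 4.12 to 0.316 ± 0.0986 CPM. Immediate early genes were higher in 22 of 47 cases and lower in 6 (camera adjusted p = 0.0333, adjusted p = 0.138 with an estimated correlation), and EGR1 (Mve13G000680) was 5.13-fold higher than at 4 mg/L.

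Ribosomal protein genes were higher in 50 of 63 cases and lower in 0, 51 and 0 adjusted over the list alone (camera adjusted p = 0.00435, adjusted p = 0.485 with an estimated correlation). This direction rested on scaling: the median of 0.24 was 0.11 with total counts (31 higher, 2 lower) and 0.03 with quantile-normalised FPKM (14 higher, 13 lower). Antioxidant genes were lower in 23 of 51 cases and higher in 7 (camera adjusted p = 0.0199, adjusted p = 0.168 with an estimated correlation). The DNA replication list (12 lower, 2 higher of 28; adjusted p = 0.0502) and the tricarboxylic acid cycle (12 lower, 5 higher of 23; adjusted p = 0.0507) lay just outside the threshold. Against the other genes and in the same direction, the first was called under 13 of 18 alternative settings and the second under 7, but neither with an estimated correlation (adjusted p = 0.211 and 0.264), and with total counts the second held 15 lower and 0 higher.

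Tissue markers differed between the hypoxic groups. Muscle genes were higher at 2 mg/L in 19 of 30 cases and lower in 4 (camera adjusted p = 0.000448, adjusted p = 0.0786 with an estimated correlation), and mantle and shell genes in 9 of 17 and 3 (camera adjusted p = 0.0333, adjusted p = 0.264 with an estimated correlation). Matrix genes, which stand beside them, were higher in 31 of 58 cases and lower in 16, 17 adjusted over the list alone (camera adjusted p = 0.0372, adjusted p = 0.265 with an estimated correlation), a call that ended without 2 mg/L replicate 1 (adjusted p = 0.0516). Digestive gland genes were lower in 15 of 21 cases and higher in 3 (camera adjusted p = 0.00449, adjusted p = 0.086 with an estimated correlation). The gonad (8 higher, 3 lower of 24; adjusted p = 0.442), hemocyte (20 higher, 17 lower of 44; adjusted p = 0.872) and neuron lists (11 higher, 3 lower of 24; adjusted p = 0.065) were not called, and the median and mean of the hemocyte list differed in sign.

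**Figure D3:**
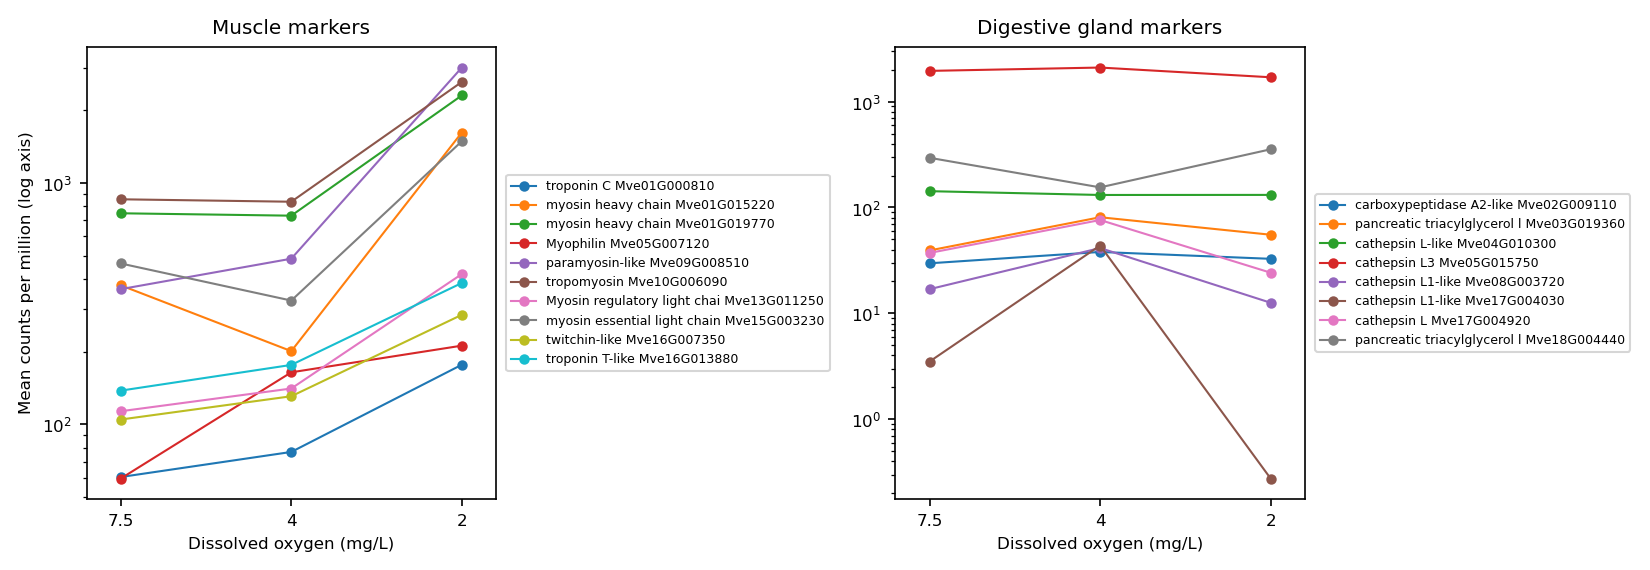
Mean CPM (log axes) at 7.5, 4 and 2 mg/L dissolved oxygen of the 10 muscle markers with a mean of at least 100 CPM over the 9 libraries (left) and the 8 digestive gland markers with a mean of at least 10 CPM (right); each line is 1 gene and each point the mean of 3 libraries. All 10 muscle markers were higher at 2 mg/L than in control, by 1.44 to 3.05 on the log2 scale.

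Differences named by the rule included genes high at 1 of the hypoxic levels. A tubulin beta chain (Mve09G011930), a microtubule subunit, was at 40.3 ± 3.92 CPM in control, 1403 ± 52.4 at 4 mg/L and 7.48 ± 1.60 at 2 mg/L, and the scaffold protein caveolin-1-like (Mve08G005800) at 2.93 ± 0.624, 57.9 ± 4.84 and 0.190 ± 0.201 CPM. In the opposite direction, the protease-binding CD109 antigen-like (Mve09G012960) was at 2.69 ± 1.14, 0.714 ± 0.227 and 139 ± 2.79 CPM and a short-chain collagen (Mve04G000630) at 3.44 ± 0.773, 1.74 ± 0.302 and 104 ± 8.43 CPM.

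A last comparison asked how far the changes at both oxygen levels coincided. Of 7515 genes changed at both, 6026 moved in the same direction, 3119 upward and 2907 downward, where independent lists would share 1715 and 1699. Log2 changes correlated across genes at 0.337 with a covariance of 0.887, against 0.490 and 0.0283 in simulated unchanged groups that share the controls. Those groups differed by library spread only, so their smaller covariance was fixed in advance and cannot show a shared response. The share of genes with the same sign, 68.8%, was close to the 66.7% of those simulated groups, so the direction of change alone says little about a shared response. Genes are not independent replicates, and the 3 controls cannot be split into parts of at least 2. Part or all of the excess over independent lists may therefore come from the shared controls. PEPCK, HIF-1alpha, C/EBP beta, BAG3 and Bcl-2-like 1 rose at both levels and serum amyloid A fell at both. Among the 6026 genes, 1309 (21.7%) went further from control at 2 than at 4 mg/L, 2087 (34.6%) were nearer to control at 2 mg/L, and 2630 were not told apart by the direct test. A further 1489 genes changed in opposite directions, 352 of them at least 2-fold in each.

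**Figure D4:**
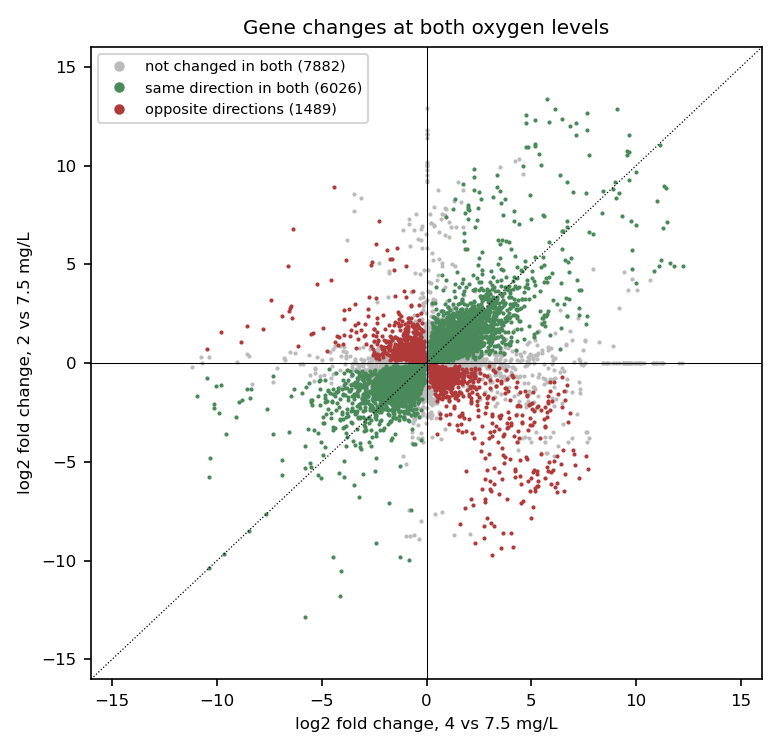
Log2 fold change of 15397 genes at 4 mg/L (horizontal axis) and 2 mg/L (vertical axis) against 7.5 mg/L; green points are the 6026 genes changed in the same direction at both levels, red the 1489 changed in opposite directions and grey the rest, and the dotted line marks equal changes.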

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

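The tests of the 3 patterns in this part and the counts over other splits of the libraries were chosen after the results were seen. Genes changed in opposite directions at the hypoxic levels were picked out because the levels differed, and there were 1489. Lists were picked out where the 2 against 4 mg/L contrast was called and their medians against control had opposite signs, although none of these lists was called against control at both levels. With total counts the antioxidant median at 4 mg/L and the innate median at 2 mg/L changed sign. Among these lists, the median log2 difference between 2 and 4 mg/L was 0.33 for heat shock proteins, -0.32 for antioxidant genes, 0.29 for innate immunity, 0.97 for muscle and -1.45 for digestive gland markers.

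Named genes higher at 4 mg/L and lower at 2 mg/L than in control differed between the hypoxic groups by these log2 values. They were -8.29 for caveolin-1-like (Mve08G005800), -7.96 for ficolin-2-like (Mve03G002320), -7.83 for DMRT4 (Mve03G009340), -7.56 for tubulin beta (Mve09G011930) and -7.34 for cathepsin L1-like (Mve17G004030). Others of this kind were HYOU1 (Mve07G000120) at -1.83, protein disulfide-isomerases A4 (Mve12G009000) at -1.44 and A3 (Mve10G009610) at -1.25, phosphofructokinase (Mve18G003940) at -0.70 and calreticulin (Mve03G001600) at -0.55. For phosphofructokinase the rise at 4 mg/L was not called with total counts or in most sets with a library left out. Its place among these genes is therefore uncertain.

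Named genes lower at 4 mg/L and higher at 2 mg/L than in control were CD109-like (Mve09G012960) at 7.59, short-chain collagen (Mve04G000630) at 5.91 and the toll-like gene (Mve11G009450) at 5.13. HSP70 12B (Mve09G007120) was at 3.26, striated myosin heavy chain (Mve01G015220) at 3.01, interferon-induced protein 44-like (Mve14G007110) at 2.56, collagen alpha-2(I)-like (Mve01G005090) at 1.94 and the lipase (Mve18G004440) at 1.19.

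The 4 mg/L group lay farther from control than the 2 mg/L group, with 10760 against 9771 genes changed, 10817 against 10330 with total counts and 10895 against 10368 with the deposited FPKM, so the size of the excess rested on the scaling. After every library was thinned to the lowest total, the ratio of the first 2 counts was 1.097 (1.095 to 1.101 in 10 further thinnings, 1.101 before), so unequal totals were not needed for it. Without the 100 most abundant genes and with scaling factors from the others, 10670 against 9683 genes changed. The ratio of the median absolute log2 changes was then 1.195. Both measures count each gene alike, so leaving out 100 genes could hardly move them. They show that the excess lay among the other genes, and cannot decide on an effect of abundant genes. There were 49 genes with at least 100 counts in each library of 1 group and at most 3 in the other 6 together (5 in control, 28 at 4 mg/L, 16 at 2 mg/L). Such genes could come from different animals in each group or from oxygen, and the design confounds them.

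Markers of other tissues moved with the groups. All 10 muscle markers with a mean of at least 100 CPM (100%) rose by at least 1 on the log2 scale at 2 mg/L, with a median of 1.65, but that mean includes the rise itself, and in the full list 17 of 30 rose, 5 fell and 8 did not pass. The median of the 10 was 8.3 times the shift between scalings, a ratio that this selection may raise. Over all 30 markers the median was 0.69 with TMM and 0.49 with total counts. With total counts 17 of the 30 rose and 8 fell, which argued against scaling as the cause of the rise. Of 8 digestive gland markers with a mean of at least 10 CPM, 6 (75%) rose at 4 mg/L and 2 fell, here counted with no fold threshold. Only 4 of the 8 rose by at least 1 on the log2 scale. This mean also includes the rise, and in the full list 13 of 21 rose and 3 fell. Most of the 8 are described as cathepsin L genes, and cathepsin L3 (Mve05G015750) was already at 1952 CPM in control gill. These genes therefore need not mark digestive gland tissue. Muscle tissue in the 2 mg/L samples, digestive gland tissue in the 4 mg/L samples and a response of gill itself to oxygen remain open, since no sample separates them.

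The 3 libraries of a group lay close together. The median coefficient of variation of genes with at least 10000 counts was at most 3.08% in the 3 groups. Repeats of one RNA pool could give this, and so could separate pools of many clams. A median does not show every gene: paramyosin and tropomyosin varied more at 2 mg/L than in control, by the SDs given above. On the third principal component (1.2% of the variance) the 2 mg/L libraries lay at -14.28, -4.52 and 18.87, and the others between -1.35 and 2.6. Whether the 2 mg/L libraries are repeats of one pool stays open. The closest pair within a group had a chi-square per degree of freedom of 5.78, but a count here is not 1 independent molecule, so its expected value is unknown and one library deposited more than once stays open. No biological explanation was tested.

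Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05, and in each the real split alone, 1 of 10, gave a count as large. For 4 against 7.5 mg/L the real split gave 10760 genes and 7 lists, and the highest other 0 genes and 4 lists. For 2 against 7.5 mg/L these were 9771 genes and 11 lists, against 0 and 6, and for 2 against 4 mg/L 9813 genes and 10 lists, against 1 and 5. Among 100 regroupings of the 9 libraries, the real one included, only the real one gave as many genes changed between any groups (12973, highest other 4027). Chance can thus be excluded for this count as far as the libraries are independent samples. For the overlap of both hypoxic levels only the real grouping was as large (6026, highest other 3785). Most regroupings called 0 genes and so had no overlap to compare, and this does not show an overlap beyond what shared controls give. If the libraries of a group share a pool, differences between clams that arose by chance are not excluded.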

How the results depend on the processing

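The settings edgeR with other scalings, DESeq2, limma on log2(FPKM + 1) and camera on log2 CPM were chosen after the data were seen. Of 2938 alternative values for the 128 pairs of named gene and comparison, 2917 kept direction and call, 17 kept direction only and 4 reversed. The 4 were catalase (Mve05G008150) at 2 against 7.5 mg/L, at -0.01 with limma on log2(FPKM + 0.1), with array weights, with limma on log2(FPKM + 1) and with edgeR scaled to total counts. None of these settings uses TMM or median-of-ratios scaling. From TMM to total counts the median log2 change of this comparison shifted by -0.199, about the size of the catalase change with TMM, so the reversal went with the scaling. With genes of a mean of at least 5 FPKM, which leaves fewer genes to test, 6248 genes changed at 4 against 7.5 mg/L, 5975 at 2 against 7.5 mg/L, 5923 at 2 against 4 mg/L and 7444 in any, with an overlap of 3710 and 7 lists at 2 against 7.5 mg/L. With an absolute log2 fold change of at least 1, a stricter threshold, the counts were 5027, 3872, 4159 and 6510. Camera with an estimated correlation called 0, 1 and 0 lists, and why it called fewer than with the preset correlation was not tested. Fry called 22, 24 and 27, but it asks whether a list's genes changed, not whether they differed from the other genes. With 69.9%, 63.5% and 63.7% of all genes called, its counts do not show that a list stood apart. Beyond the losses with an estimated correlation and with a library left out, the calls of these lists ended under 1 or more filters, pseudocounts, scalings or list tests: at 4 against 7.5 mg/L immediate early and digestive gland, at 2 against 7.5 mg/L heat shock, antioxidant, apoptosis, DNA replication, matrix, cilia and mantle, and at 2 against 4 mg/L endoplasmic reticulum stress, antioxidant, innate, ribosomal, matrix and mantle. The other settings left the counts of genes and lists within 1.5 times.

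With a library left out in turn, genes changed ranged from 10124 to 10780, 9146 to 9746 and 9182 to 9758 in the 3 comparisons, from 12572 to 12760 in any and from 5565 to 5830 in the overlap. Lists ranged from 5 to 7, 10 to 12 and 9 to 12. The replicate block gave 10519, 9508 and 9531 genes, 12722 in any, an overlap of 5827, and 7, 11 and 12 lists. Replicate numbers do not pair the samples: correlations of deviations from the group means were -0.033 to 0.012 for the same number and -0.023 to 0.03 for different numbers. Depth limits genes with few counts: the coefficient of variation in control was 30.22% for genes with a mean from 20 counts and 2.6% from 10000.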

Other observations

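The tests of the genes in this part were planned, and no hypothesis was tested here. The single genes given here stand apart from their lists, none of which was called at either hypoxic level against control. The glucose transporter GLUT1-like (Mve04G001160), which admits sugar for glycolysis, rose from 10.3 ± 1.46 CPM in control to 49.5 ± 3.11 at 4 mg/L and 88.8 ± 6.48 at 2 mg/L. Monocarboxylate transporter 5-like (Mve07G009680) was at 155 ± 10.2, 435 ± 14.7 and 379 ± 12.7 CPM, and ATP-citrate synthase (Mve12G006360), which makes cytosolic acetyl-CoA, at 16.5 ± 0.511, 69.7 ± 1.97 and 54.6 ± 3.76 CPM. Fatty acid synthase (Mve01G012410), which uses that acetyl-CoA, fell at both levels, from 27.2 ± 3 to 17.9 ± 2.54 and 5.40 ± 0.400 CPM. The interleukin 17-like cytokine (Mve11G002500) rose at both, from 35.2 ± 4.90 to 75.3 ± 3.08 and 153 ± 9 CPM.

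The betaine transporter (Mve06G010360), which takes up an osmolyte of marine bivalves, was at 88.5 ± 6.50 CPM in control, 5.12 ± 0.209 at 4 mg/L and 25 ± 1.71 at 2 mg/L, and aquaporin-5-like (Mve06G006830), a water channel, at 84.8 ± 5.06, 10.5 ± 0.650 and 15.6 ± 2.37 CPM. The creatine transporter (Mve09G006690) was at 209 ± 4.16, 93.3 ± 1.08 and 85.3 ± 2.60 CPM. At 4 mg/L 2 carbonic anhydrase genes, whose enzymes interconvert carbon dioxide and bicarbonate, went opposite ways. The GPI-anchored form (Mve11G016400) was at 12.8-fold higher at 4 mg/L than in control and 1.41-fold higher at 2 mg/L (18.2 ± 0.808 CPM in control and 25.8 ± 1.47 at 2 mg/L), and carbonic anhydrase II (Mve06G005770) at 119 ± 4.21, 42.5 ± 2.02 and 106 ± 2.05 CPM. The multidrug transporter ABCB (Mve12G003520) was at 30 ± 0.939, 171 ± 1.65 and 36.8 ± 3.76 CPM. All values are mean ± SD, n = 3.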
